A study of Drosophila melanogaster with 2 samples.

How the data were processed

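Chromatin from whole white prepupae, pooled males and females, of a line expressing Hr39 with a C-terminal GFP was sheared by sonication to a size range of 200 to 800 and precipitated with an anti-GFP antibody, per the labels. The labels name 2 biological replicates, 1 and 3; both are given as separate samples of 1 strain. The authors deposited, for each of the builds dm6 and dm3, a candidate region list per replicate, a candidate list from both replicates pooled, and an optimal set that passed a threshold on the irreproducible discovery rate (IDR), which compares ranks between replicates. Per the deposited notes on the libraries, candidate lists were made from the alignments of 1 replicate or of both together with 1 control alignment. The peak caller, aligner and their versions are not given in the sources used here. The control alignment was not analysed here.

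The signal value of each region was set by the authors; it was not scaled to depth, as the pooled maximum (6049) is near the sum of the replicate maxima (3119 and 2962), and was used only to rank regions within a list. The authors deposited −log10 q values per region, which ran from 2.88 to 3.62 in the optimal set and were not used for ranking. Summit positions were taken from the deposited offsets. The optimal set of 7444 regions was exactly the part of the pooled list of 28773 regions with the highest signal. The dm6 candidate list of each replicate held 30000 regions. Peak lists give no read counts, so depth is unknown and no interval from counting reads is given.

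Regions on the arms 2L, 2R, 3L, 3R, 4 and X were analysed, which left out 18 optimal regions on the mitochondrial genome. All region ends lay within the arm lengths of the reference genome, and genes, TSSs, exons and coding sequence came from the Ensembl 115 annotation of the same coordinates, without transposable elements. The dm3 lists gave only counts of peaks per arm, and no coordinates were converted. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

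Replicate values came from the 7426 highest-signal regions of each replicate. Summits within 100 bp counted as shared, and chance was set by 1000 circular shifts within arms. Each summit had 1 class, in the order promoter (within 1000 bp of a TSS of any gene), coding exon, UTR or non-coding exon, intron and intergenic, and was compared with 1000 draws of random positions on the same arms. Matches to 12 motifs on either strand within 50 bp of summits were compared with windows centred 500 bp to each side by Fisher's exact test, with odds ratios and 95% intervals on the log scale. Rank trends used 100000 permutations. Gene lists were tested by Fisher's exact test on protein-coding genes with a summit within 1000 bp of any TSS, and gene bodies against 10000 lists matched in 20 bins of gene length. All tests were two-sided, and families of tests were Benjamini-Hochberg adjusted.

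Groups, tests, gene lists, motifs and most alternatives were fixed before the data were examined. The names given in the text follow a rule fixed at the same time: Hr39; the nearest protein-coding gene of the 15 highest-signal peaks; up to 4 members with and 2 without a promoter peak for lists that passed the threshold, up to 2 and 1 for other lists; and every ecdysone-response factor or nuclear receptor with a peak at its promoter or gene body. In 11 cases a list name was replaced by the symbol the annotation uses, 1 name was left out because it matched no gene, and 2 genes that only shared a prefix with a family (Cpr and Cyp40) were removed by name before values were seen. Alternatives were other distances, windows and flanks, the part of the optimal set with signal above its median, another background, distal peaks alone, and each replicate alone. Alternatives chosen after the data were seen include positions matched to each summit on arm and on the number of G and C bases, over 1000 bp from any pooled candidate.

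The statistics were tested on simulated data. With 59.7% of 7426 regions truly shared, 60.0% were recovered. Random gene lists without an effect gave 2 calls, and of 120 lists of 100 genes with odds raised 3 times, 119 were called. The NR5 element against matched positions, with none planted, had a mean odds ratio of 1.08 over 20 simulations, of which 1 passed a threshold of 0.05. Simulated summits and their matched positions were drawn from the same positions away from optimal peaks. These runs therefore check the calculation, and not whether matched positions are a fair background for real summits.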

Results

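Genome-wide occupancy of Hr39, an orphan nuclear receptor of the NR5 (Ftz-F1) family, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in *Drosophila melanogaster* at the white prepupa stage, the brief immobile stage that opens metamorphosis after the late larval pulse of the steroid hormone ecdysone. Whole animals of both sexes carried an Hr39 protein fused at its C terminus to eGFP, and chromatin was precipitated with an antibody against GFP. The samples form 1 group with 2 biological replicates, numbered 1 and 3. No second condition was analysed here, so the comparisons are between replicates, between peaks and background positions, and between groups of genes. No precipitation from animals without the fusion protein was analysed here, so peaks that depend on Hr39 were not told apart from other signal. The sequencing depth of the replicates is unknown from the peak lists, and no read counts enter the values below. All coordinates are on dm6.

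The replicates placed their strongest regions at the same positions. The optimal set held 7444 regions, of which 7426 lay on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. Among the 7426 regions with the highest signal in each replicate, 80.1% of those of replicate 1 had a summit within 100 bp of one from replicate 3, against a mean of 1.13% after circular shifts of the summits along the arms (permutation p = 0.001, the smallest that 1000 shifts can give). Among 14243 candidate regions matched between the replicates, the rank correlation of the authors' signal across regions was 0.888 and the median distance between matched summits was 23 bp. Regions are not independent replicates, so no p-value is given for it. Over the full candidate lists, which include background regions, 47.5% of the regions of replicate 1 were shared. Of the 7426 optimal summits, 95.1% had a candidate summit of replicate 1 within 100 bp and 98.4% one of replicate 3. Membership of the optimal set therefore does not mean that both replicates had a candidate region there.

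Among the 15 highest-signal peaks, 11 lay within 1000 bp of an annotated transcription start site (TSS), 4 in introns and 0 in exons outside promoters. The strongest summit, at position 19590614 of 3L (region 19590400 to 19590833, signal 6049), lay 90 bp from the nearest TSS of a protein-coding gene, CG14100, and ranked 1 in both replicates. The next was in an intron, 1370 bp from the TSS of cbt (cabut, a zinc finger transcription factor), in region 480843 to 481327 of 2L, ranked 2 in replicate 1 and 3 in replicate 3. Peaks near Ugalt (a UDP-galactose transporter; region 2703670 to 2704117 of X, 42 bp from the TSS) and PNPase (a mitochondrial RNA-degrading enzyme; region 31404449 to 31404901 of 3R, 85 bp) followed. Chro (Chromator, a chromosome and spindle protein) had a peak 90 bp from its TSS. CG1888, Lk6 (a kinase of translation initiation factor eIF4E), Art3, Tcs5 and CenG1A had summits between 105 and 968 bp from theirs. The remaining nearest genes were CG16753, osa (a subunit of the Brahma chromatin remodelling complex), CG32772, larp and CG11050. The summit nearest osa lay 13931 bp from the closest protein-coding TSS and within 1000 bp of the TSS of a gene that is not protein-coding. The ranks of these 15 peaks did not exceed 19 in replicate 1 and 16 in replicate 3.

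Hr39 itself had 2 peaks in the optimal set, both in introns of the gene (2L, 21237250 to 21259675), and no promoter peak in that set. The stronger, in region 21250782 to 21251183, ranked 147 in the optimal set, 410 in replicate 1 and 78 in replicate 3. The weaker, in region 21244118 to 21244310, ranked 2102 in the optimal set and 1755 in replicate 3, with no region of replicate 1 within 100 bp. With 20 kb added to each side of the gene, the count of 2 compared with a median of 4 in windows of the same length around the other 13944 protein-coding genes, and 20.6% of windows held fewer. The replicates differed here: 7 of the top regions of replicate 3 and 1 of those of replicate 1 fell in the window. Among the 7 was a region at an Hr39 promoter (21237551 to 21237940, rank 3934 in replicate 3).

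Promoters held more summits than random positions did, and coding exons held very few. Of the optimal peaks, 47.4% had a summit within 1000 bp of a TSS, against 23.6% of random positions on the same arms, a ratio of 2.01 (permutation p = 0.001, two-sided, the smallest that 1000 draws can give). The share was 48.2% ± 3.06 (SD, n = 2) across the top regions of the replicates. Coding exons outside promoters held 6 summits, or 0.0808%, against 10.6% of random positions. UTRs and non-coding exons held 1.39% against 4.55%, and intergenic sequence 15.3% against 24.97% (permutation p = 0.001 for each of these 3 classes). Introns held 35.8% of summits and 36.3% of random positions, a difference that did not pass the test (permutation p = 0.373); in the top regions of replicate 3 alone the ratio was 0.930 (permutation p = 0.001). The promoter share was 63.9% in the highest-signal bin of 10 equal bins of the peaks and 40.2% in the lowest.

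**Figure D1:**
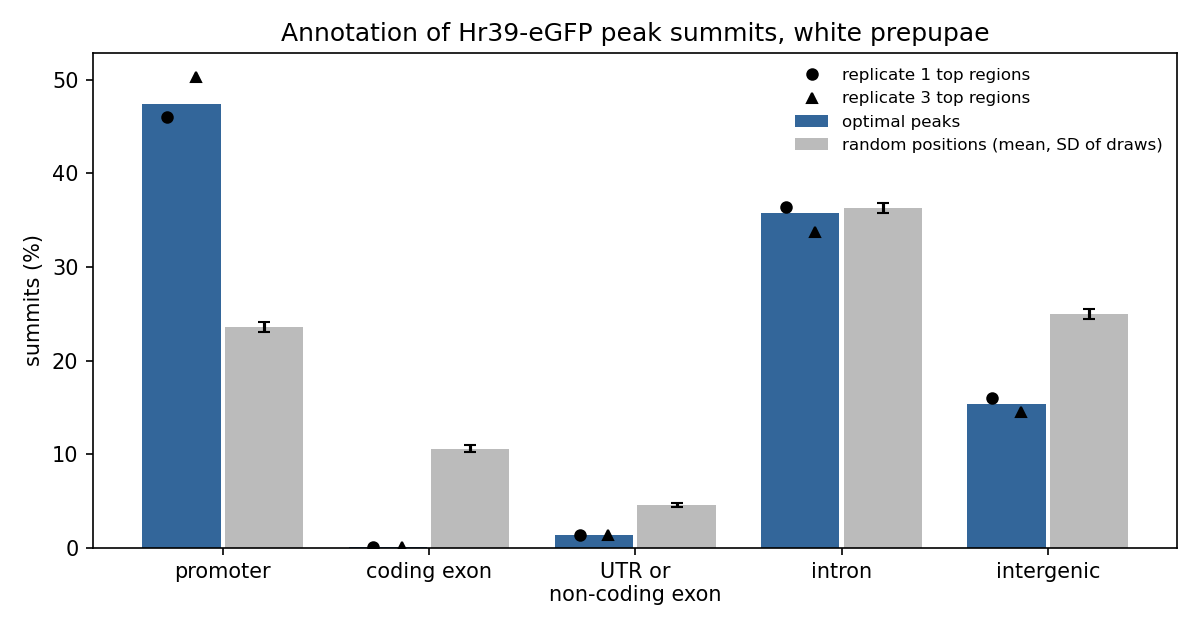
Share of summits (y axis, %) in 5 annotation classes (x axis), for optimal peaks (blue bars), random positions on the same arms (grey bars, mean with the SD of 1000 draws) and the top regions of each replicate (circles, replicate 1; triangles, replicate 3). Promoters held 47.4% of optimal summits against 23.6% of random positions, and coding exons 0.0808% against 10.6%.

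A promoter peak was present at 3514 of 13945 protein-coding genes (25.2%), with 3401 genes in replicate 1, 3907 in replicate 3 and 3071 in both. Of 24 gene lists fixed before the data were examined, 7 had promoter peaks at more of their members than other genes had and 7 at fewer (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 24 lists, threshold 0.05). The calls for ribosomal proteins, cuticle proteins, chemoreceptors and the cytochrome P450, GST and UGT genes held under all 7 alternatives tried, and the other 10 were lost under at least 1. Each list is given with its adjusted exact p from this test, and the rank given for a gene with a promoter peak is that of its strongest promoter peak. The test counts genes as independent. However, neighbours can share a region, as ERR and Atg18a do, and family members can lie close together, as Cpr47Ec and Cpr47Ed on 2R do. The p-values of lists with such members may therefore be too small.

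Of 14 ecdysone-response transcription factors, 8 (57.1%) had a promoter peak (odds ratio 3.89, 95% interval 1.40 to 10.8, adjusted exact p = 0.0266), and the count was 8 in each replicate. Hr3, an early-late nuclear receptor, had 2 promoter peaks, the stronger at rank 474 and 393 bp from a TSS. Eip75B, a heme-binding nuclear receptor of the early response, had 3 promoter peaks and 15 over its whole locus; an intronic peak whose nearest protein-coding TSS is that of Eip75B ranked 17 (region 18011668 to 18012116 of 3L). EcR, the ecdysone receptor, had 3 promoter peaks and its partner usp 2. The strongest promoter peak of EcR, at rank 2606, had no candidate region of replicate 1 within 100 bp. Eip74EF and Blimp-1 had 2 promoter peaks each. At br (Broad) and Eip93F, regulators of the pupal and adult programmes, there was 1 each, at ranks 6425 and 6643. Hr39, Eip78C, Hr4, ftz-f1 and Kr-h1 had peaks in or beside the gene body and none at a promoter; the strongest of Eip78C ranked 60 (region 21253681 to 21254101 of 3L) and that of Hr4 82 (region 1951730 to 1952101 of X). Of the 14, crol had no peak over its locus. Tested over gene bodies against lists matched on gene length, 13 of the 14 had a peak against 65.7% in matched lists, and the call was lost (permutation test, adjusted p = 0.102). It was also lost with the TSS distance set to 500 bp (adjusted exact p = 0.291), in the top regions of replicate 3 alone (0.057), in the optimal peaks with signal above their median (0.0619) and with the gene 5′ end alone (0.0571).

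Of 21 nuclear receptors, 9 had a promoter peak (42.9%), which did not pass the test (adjusted exact p = 0.123); over gene bodies 17 of 21 did, against 54.0% in length-matched lists (permutation test, adjusted p = 0.0315). ERR, a regulator of glycolytic metabolism, had a promoter peak at rank 459 in a region that it shares with Atg18a. Hr96, a receptor in dietary lipid handling, had one at rank 586, Hnf4 at 1900, eg at 4992 and Hr78 at 6236. The peaks of knrl, Hr51, Hr38 and svp lay in or beside gene bodies and not at promoters, at ranks 983, 2722, 2828 and 6904, and dsf had none. Among 16 genes of ecdysteroid synthesis, transport and inactivation, 5 had a promoter peak (adjusted exact p = 0.681), among them E23, an ecdysone-responsive transporter (rank 389), and Oatp74D, the ecdysone importer (rank 2215), and not Cyp18a1, which inactivates the hormone.

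With all optimal peaks and 1000 bp to a TSS, ribosomal protein genes had the highest share of all lists. A promoter peak lay at 67 of 93 cytoplasmic ribosomal protein genes, 72.0% against 24.9% of other genes (odds ratio 7.69, 95% interval 4.90 to 12.1, adjusted exact p = 6.22e-20), and the replicate shares were 73.1% ± 7.60 (SD, n = 2). RpS19b, RpS27, RpL34b and RpL32 had the strongest, at ranks 230, 261, 366 and 435, whereas RpL10Aa and RpL11 had none. The 88 genes of the mitochondrial respiratory chain did not stand apart, with 24 (27.3%; adjusted exact p = 0.681), including ND-MWFE and ND-ASHI and not ATPsynB.

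The other lists with more promoter peaks were Notch and EGFR signalling, lipid and sterol metabolism, imaginal disc morphogenesis, insulin and TOR signalling, and autophagy. Of 24 genes in the Notch and EGFR list, 13 had one (odds ratio 3.49, adjusted exact p = 0.0127). They included the EGFR ligand spi (rank 196), the kinase Raf (rank 417) and E(spl)m3-HLH, a Notch target (rank 832). Also among them was stg (rank 334), a Cdc25 phosphatase of the cell cycle that the fixed list holds. Delta and E(spl)m5-HLH had none. Lipid and sterol metabolism had 14 of 27 (odds ratio 3.20, adjusted exact p = 0.0127), led by Lpin (rank 100), a phosphatidate phosphatase, then SREBP, the triglyceride lipase bmm and the carnitine palmitoyltransferase whd; ATPCL and FASN2 had none. Imaginal disc morphogenesis had 7 of 11 (adjusted exact p = 0.0266), with Ldh, RhoGEF2, sqh (the myosin regulatory light chain) and ImpE2 leading, and none at ImpE1 and ImpL1. Insulin and TOR signalling had 10 of 19 (adjusted exact p = 0.0292), with melt, mTor, Pi3K21B and Pi3K92E leading and none at chico and gig. The promoter peak of mTor had no candidate region of replicate 3 within 100 bp. Autophagy had 10 of 21 (adjusted exact p = 0.0455), with Atg17, Atg18a, Atg2 and Atg9 leading and none at Atg1 and Atg10. The calls for the imaginal disc, autophagy, lipid and insulin lists were lost when gene bodies were tested against length-matched lists (permutation test, adjusted p between 0.105 and 0.311). They were also lost in the optimal peaks with signal above their median (adjusted exact p between 0.066 and 0.241). The Notch and EGFR call and the lipid call were lost with the TSS distance set to 500 bp (adjusted exact p = 0.130 and 0.107), and the imaginal disc, lipid and insulin calls with the gene 5′ end alone (adjusted exact p = 0.0571, 0.075 and 0.0571). In single replicates, the imaginal disc call was lost in replicate 1 (adjusted exact p = 0.0523) and the insulin and TOR call in replicate 3 (adjusted exact p = 0.117).

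**Figure D2:**
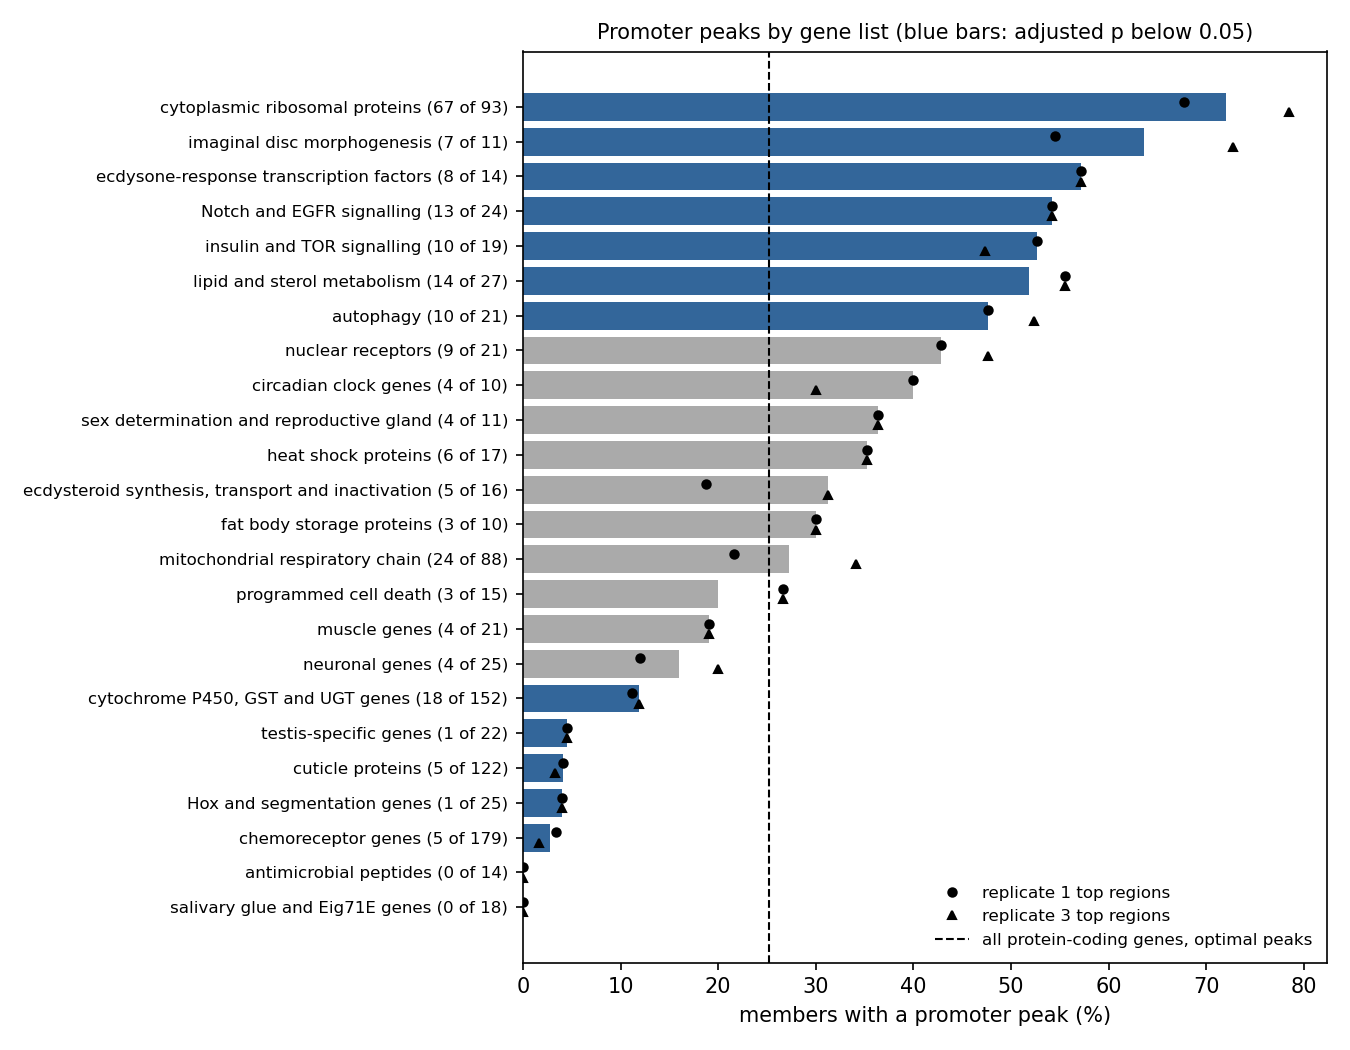
Share of members with a promoter peak (x axis, %) for each of 24 gene lists (y axis, with counts). Bars are optimal peaks, blue where the adjusted exact p was below 0.05; circles and triangles are the top regions of replicates 1 and 3, and the dashed line marks the 25.2% of all protein-coding genes. Ribosomal protein genes reached 72.0%, and salivary glue genes and antimicrobial peptides 0%.

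The lists with fewer promoter peaks were cuticle proteins, salivary glue and Eig71E genes, chemoreceptors, cytochrome P450, GST and UGT genes, Hox and segmentation genes, testis-specific genes and antimicrobial peptides. Cuticle proteins had 5 of 122 (4.10%; odds ratio 0.138, adjusted exact p = 5.38e-09), at Cpr62Ba, Cpr72Eb, Cpr47Ec, Cpr47Ed and Cpr49Ah, and none at Acp65Aa or Ccp84Aa. Salivary glue and Eig71E genes, known from the larval and prepupal salivary gland, had 0 of 18 (adjusted exact p = 0.0266), Eig71Ea and Eig71Eb among them. Chemoreceptor genes had 5 of 179 (adjusted exact p = 2.58e-15), at Ir94h, Or88a, Or9a, Ir67c and Ir60a and not at Gr10a or Gr10b; Ir60a and Cpr49Ah were named after their values were seen. Cytochrome P450, GST and UGT genes had 18 of 152 (11.8%, adjusted exact p = 0.000401), although GstE13 ranked 29 and Cyp6u1 239; Cyp310a1 and Cyp6v1 also had one, and Cyp12a4 and Cyp12a5 had none. Hox and segmentation genes had 1 of 25 (adjusted exact p = 0.0266), at Antp (rank 7338) and not at abd-A or Abd-B. Testis-specific genes had 1 of 22 (adjusted exact p = 0.0455), at can, and none at achi or aly. Antimicrobial peptides, AttA and AttB among them, had 0 of 14 (adjusted exact p = 0.0479). The salivary glue, Hox, antimicrobial and testis calls were lost over gene bodies against length-matched lists (permutation test, adjusted p = 0.155, 0.093, 0.311 and 0.194) and in the optimal peaks with signal above their median (adjusted exact p = 0.196, 0.066, 0.251 and 0.337). The salivary glue, Hox and antimicrobial calls were lost with the TSS distance set to 500 bp (adjusted exact p = 0.0532, 0.062 and 0.103), and the antimicrobial call also at a wider distance (adjusted exact p = 0.375). The antimicrobial and testis calls were lost with the gene 5′ end alone (adjusted exact p = 0.087 and 0.075) and in replicate 1 alone (adjusted exact p = 0.0523 and 0.0507).

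The other lists did not pass the test on promoter peaks. Programmed cell death had 3 of 15 (adjusted exact p = 0.774), including the pro-apoptotic gene hid at rank 156 and Diap1 at 593, and not Buffy. Heat shock proteins had 6 of 17 (adjusted exact p = 0.533), with Hsp27 at rank 88, Hsp26 at 846 and none at Hsf. Neuronal genes had 4 of 25 (adjusted exact p = 0.511), with elav and Syx1A and not Ace; over gene bodies the list was lower, with 8 of 25 against 60.4% in length-matched lists (permutation test, adjusted p = 0.0116). Muscle genes had 4 of 21 (adjusted exact p = 0.681), with Zasp52 and sls and not Act57B. Circadian clock genes had 4 of 10 (adjusted exact p = 0.425), with cry and dco and not Clk. Sex determination and reproductive gland genes had 4 of 11 (adjusted exact p = 0.613), with Sxl and ix and not Abd-B. Fat body storage proteins had 3 of 10 (adjusted exact p = 0.751), with Mtp and Apoltp and not Fbp1.

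Summits were AT-rich. GC content within 50 bp of optimal summits averaged 33.9% ± 8.10 (SD over 7426 summits), against 43.8% ± 7.41 in windows 500 bp to each side and 42.2% over the 6 arms. The summit was lower than its flanks at 82.2% of peaks; the summit mean was 34.4% in replicate 1 and 33.7% in replicate 3. Of 8192 7-mers, 1865 were more frequent at summits and 3345 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05). TTTAAAA led, in 13.7% of summit windows and 4.40% of flanks (adjusted exact p = 3.02e-123). Of the 512 7-mers with at most 1 G or C base, 504 were more frequent at summits. The 7-mers were not tested against positions matched on composition, so single sequences were not told apart from the AT-rich composition. Among the more frequent 7-mers with at least 3 G or C bases, CTATCGA had the smallest p, in 2.17% against 0.593%.

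The response element of NR5 receptors, YCAAGGYCR, was not more frequent at optimal summits than in their flanks. It lay within 50 bp of 39 summits (0.525%) against 0.471% of flank windows (odds ratio 1.12, 95% interval 0.759 to 1.66; Fisher's exact test over windows, adjusted p = 0.666 over 12 motifs). The replicate shares were 0.471% and 0.606%. Against positions matched on arm and base composition, a background chosen after the data were seen, the odds ratio was 1.98 (95% interval 1.41 to 2.79, adjusted exact p = 0.00155). The reversed sequence, a control of the same composition, gave 1.17 (0.713 to 1.92). Positions matched in this way lay at promoters in 19.4% of cases, against 47.4% of optimal summits. The ratio of 1.98 is therefore not corrected for promoter share. Against flanks the reversed sequence was lower at summits (0.229% against 0.451%; odds ratio 0.517, adjusted exact p = 0.0209). Inside the optimal set, a trend of presence with rank did not pass the test (Spearman rho = 0.021, permutation p = 0.0682). The share was between 0.269% and 0.538% in bins 1 to 5 of 10 equal bins, 1 being the highest signal, and between 0.270% and 1.08% in bins 6 to 10. In simulations against flanks, a planted share of 0.5% was called in 19 of 20 runs and one of 0.25% in 14 of 20. The simulated summits were random positions, which lack the lower GC content of real summits than of their flanks. These runs therefore do not give the power of the test at real summits.

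**Figure D3:**
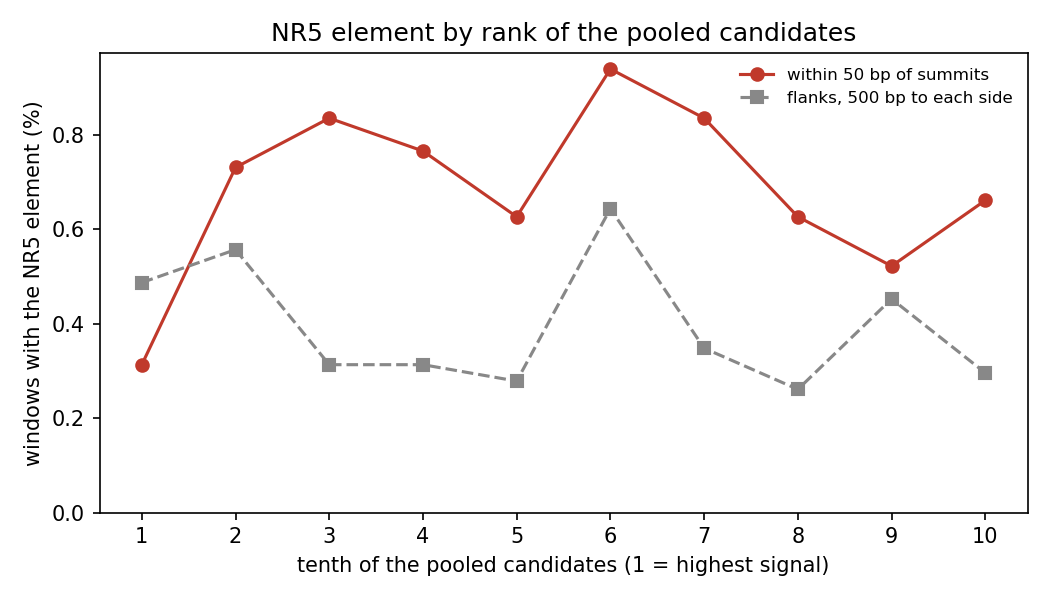
Windows with the NR5 response element (y axis, %) in 10 equal bins of the pooled candidates by signal (x axis, 1 the highest), within 50 bp of summits (red circles) and in flanks 500 bp to each side (grey squares). In bin 1 summits had 0.313% and flanks 0.487%, and in bins 2 to 10 the summit share was above that of the flanks.

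Promoter elements of housekeeping genes were enriched under both backgrounds. Neither background was matched on distance to a TSS, and matched positions lay at promoters in 19.4% of cases against 47.4% of summits. The enrichment was therefore not separated from the promoter share of the peaks. The DNA replication-related element (DRE), TATCGATA, lay at 1.23% of summits and 0.222% of flanks (odds ratio 5.52, 95% interval 3.71 to 8.21, adjusted exact p = 9.56e-19), and its odds ratio against matched positions was 3.30. Motif 1, YGGTCACACT, reached 0.417% against 0.0606% (odds ratio 6.66, adjusted exact p = 5.18e-08; 8.003 against matched positions). The GATA element was higher at summits than in flanks (odds ratio 1.40, adjusted exact p = 0.0209), but not against matched positions (1.05, adjusted exact p = 0.742). The GAGA element and the E-box were lower than in flanks (odds ratios 0.361 and 0.498, adjusted exact p = 5.27e-17 and 1.68e-05), and neither passed the test against matched positions (odds ratios 1.30 and 0.930, adjusted exact p = 0.131 and 0.742). The nuclear receptor half-sites AAGGTCA and AGGTCA, the Zelda element and the AP-1 element did not pass the test (adjusted exact p = 1, 0.0779, 0.0834 and 0.0974). The inverted repeat bound by EcR and usp was found at 0 summits and in 2 of 14852 flank windows (adjusted exact p = 0.666). Matches to it were too rare for the test to show a lack at summits.

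**Figure D4:**
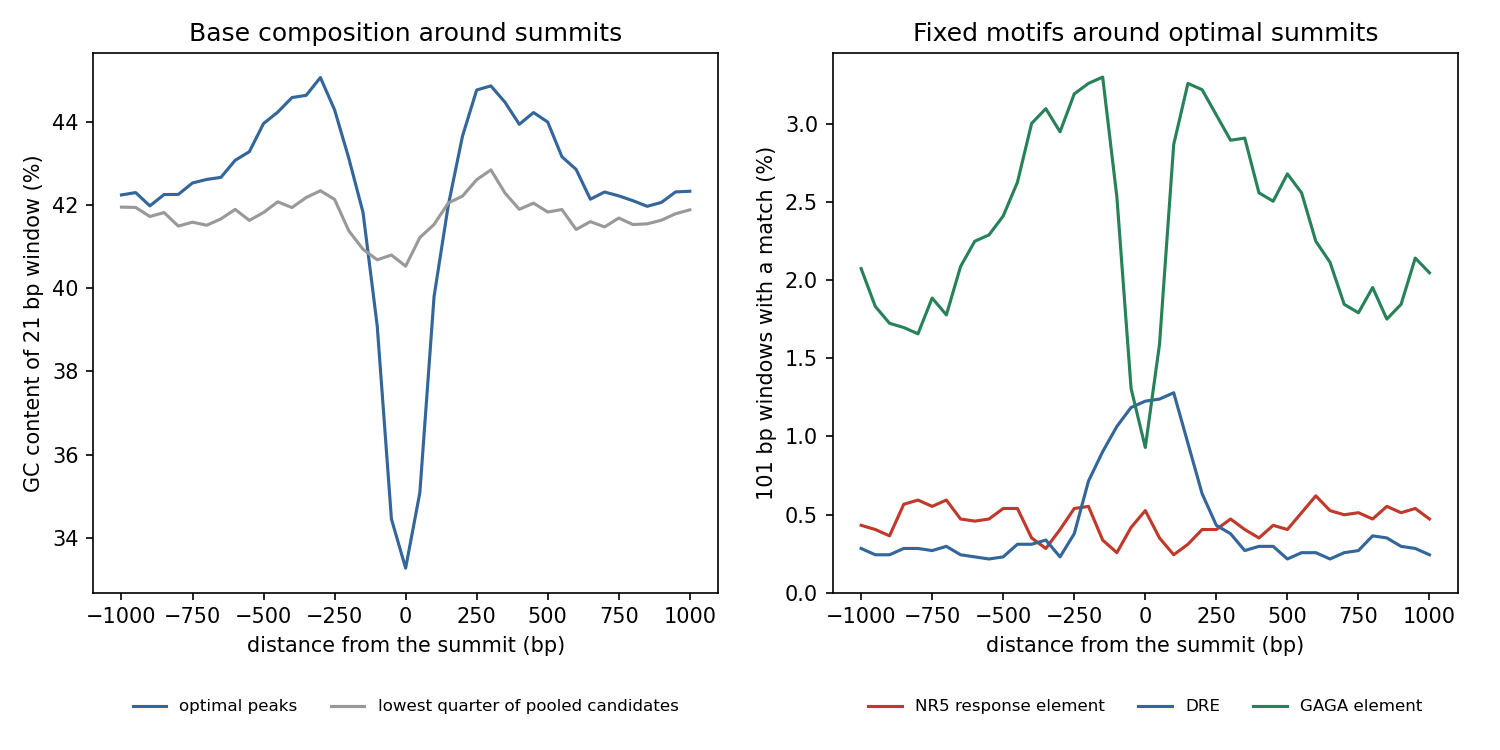
Left, GC content (y axis, %) by distance from the summit (x axis, bp) for optimal peaks (blue) and for the pooled candidates of lowest signal, a share of 0.25 of the list (grey). Right, windows with a match (y axis, %) to the NR5 response element, the DRE and the GAGA element around optimal summits. GC content dips to 33.3% at the optimal summits, and the DRE is at 1.23% there.

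Peaks were denser on X than on the large autosome arms. There were 0.684 optimal peaks per protein-coding gene on X and 0.506 on 2L, 2R, 3L and 3R, a ratio of 1.35, with 1.39 in replicate 1 and 1.30 in replicate 3. Per Mb of sequence there were 63.8 peaks on X and between 49.8 and 56.5 on these autosome arms. The share of genes with a promoter peak was 27.9% on X and 24.7% on the autosome arms (odds ratio 1.18, 95% interval 1.06 to 1.31; Fisher's exact test, two-sided, p = 0.00172). The top regions of replicate 3 alone did not pass this test (exact p = 0.0921), nor did the optimal peaks with signal above their median, for which the odds ratio was 0.992 (exact p = 0.899).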

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

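Regions outside the comparisons were flagged where they numbered more than 3, a cut-off that is not a test of excess. The dm6 optimal set had 18 regions on the mitochondrial genome, and the dm3 optimal set had 15 on contigs outside the 6 arms; no explanation was tested for either. With 2 samples in 1 group, no sample was set against the rest and no effect was compared between groups.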

How the results depend on the processing

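Under every alternative tried, the same side of the threshold and direction held for the replicate overlap (67.01% to 84.6%) and the promoter share (36.7% to 60.2%; single replicates 46.0% to 50.4%). No pairing of samples was possible because there is 1 group. Summits could have been paired with their own flanks, but no such test was run. The backgrounds matched on composition, the candidates below the optimal set, and the alternatives for the rank correlation, annotation classes and 7-mers were chosen after the data were seen. The cause was not tested for the changes below unless stated. The rank correlation was 0.912 with summits within 50 bp and 0.875 within 250 bp. The ratio of introns to background was 0.928 in the stronger part of the optimal peaks (signal above their median) and 0.891 against matched positions, both past the threshold, and 0.930 to 1.00 in single replicates. The odds ratio of the NR5 element was 0.808 with 100 bp to the summit, 0.665 in the stronger part of the peaks, 0.921 against the pooled candidates of lowest signal, 0.885 for peaks over 1000 bp from a TSS, and 0.893 to 1.19 in single replicates, none past the threshold; it was past it at 1.98 against matched positions and 2.02 in candidates below the optimal set. Genes with a promoter peak numbered 2225 in the stronger part, which holds fewer peaks. Lists with more promoter peaks numbered 4 at 500 bp, 2 in the stronger part, 3 with the gene 5′ end alone and 3 over gene bodies; lists with fewer numbered 4, 3, 5 and 4. Single replicates gave 5 to 6 and 5 to 7. The X ratio was 1.31 in the stronger part, where the odds of genes turned to 0.992, and 1.30 to 1.39 in single replicates. Peaks at Hr39 numbered 1 to 7 in single replicates. Uncalled lists that crossed the share of other genes were ecdysteroid genes (12.5% in the stronger part, 18.8% in replicate 1, 31.2% over gene bodies), cell death (26.7% in replicate 1), fat body (30% at the wider TSS distance, 10% in the stronger part), respiratory chain (15.9% in the stronger part, 21.6% in replicate 1, whereas the 34.1% in replicate 3 did not cross), clock (20% at the 5′ end, 40% over gene bodies) and sex determination (9.09% at 500 bp and at the 5′ end). Unknown read depth limits all values per replicate.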

Other observations

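Peak counts per locus, not scaled to its length, were highest at the following genes, which were chosen after their values were seen. kirre, an immunoglobulin-family gene of myoblast fusion on X, had 36 optimal peaks over its locus, the highest count of any protein-coding gene, and 0 at its promoters. sbb and CG1677 had 22 each, Tet and Ptp61F 20 each, and CG43658, Mnt and shn 18 each. Of the genes with a promoter peak, 2771 had 1, 591 had 2 and 152 had 3 or more.

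Chromosome 4 differed between the replicates, with 47 candidate regions in replicate 1 and 299 in replicate 3, and 15 and 34 among their top regions. The dm6 candidate lists had 1 mitochondrial region in replicate 1 and 28 in replicate 3.

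All tests below were chosen after the patterns were seen; for the matched positions in coding exons and the windows around other genes, the outcome had not been seen when the test was set. No biological explanation was tested, since the samples form 1 group.

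The NR5 element showed no excess over flanks at optimal summits. Base composition remains open as a candidate cause: against positions of the same composition the odds ratio was 1.98, and the reversed sequence rose from 0.517 against flanks to 1.17. Those positions also lay at promoters less often than summits did (19.4% against 47.4%). A difference between strong and weak regions also remains open, since candidates below the optimal set had 2.02 (95% interval 1.62 to 2.52). The difference from the optimal set was not tested. Over all 28752 pooled candidates, a trend of presence with rank did not pass the test (Spearman rho = 0.003, permutation p = 0.591). That trend concerns presence at summits and not the ratio to flanks. For dilution by promoter peaks, the odds ratio among peaks over 1000 bp from a TSS was 0.885 with an interval of 0.504 to 1.56, too wide to decide. Against flanks, the reversed sequence had 0.425 among these peaks (95% interval 0.182 to 0.992). In candidates below the optimal set it had 0.673 (0.505 to 0.897). A control of the same composition was thus rarer at summits than in flanks in both sets. AT-rich summits may hide a modest excess of the element, but similar composition went with different ratios to flanks. In bin 1 of the pooled candidates, summits had 33.0% GC and flanks 44.2%, and the odds ratio was 0.665 (95% interval 0.319 to 1.39). In bin 2, with 34.2% and 43.6%, it was 1.33 (0.767 to 2.29). In bin 3, with 34.8% and 43.5%, it was 2.66 (1.45 to 4.88). The bins were not compared by a test.

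Only 6 optimal summits lay in coding exons outside promoters. Base composition is argued against as the whole cause, since positions matched on it lay there in 4.36% of cases (3.95% to 4.98% over 100 draws). An avoidance by the strongest regions alone is argued against too, since candidates below the optimal set had 2.22%, under the lowest of 1000 random draws (9.92%). What remains was not tested.

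The top regions of replicate 3 exceeded those of replicate 1 by 6 at the Hr39 locus, and the full candidate lists held 11 and 1 regions there. A general difference between the lists is argued against, since 0.373% of windows around protein-coding genes differed as much in that direction. Summits of the 7 regions had a mean GC content of 42.4% ± 6.35 (SD over regions), against 33.7% in all top regions of replicate 3 (permutation p = 0.00516), which is consistent with reads raised over the whole locus by transgene copies. This test is weak, because the GC content of the 2 optimal peaks there had been seen, and because both replicates carry 1 strain, so copies alone do not give a difference between them. Differences in the control or in the animals were not tested.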
